A study of Mus musculus with 8 samples.

How the data were processed

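RNA of mouse epididymal white adipose tissue was measured on 8 Affymetrix U74Av2 arrays, 1 for each combination of genotype and treatment, so each of the 8 groups held 1 array. Wild type mice and mice lacking Ppara were either controls or given the β3-adrenergic agonist CL 316243, as 30 nmol for 8 hours or at 3 nmol per hour for 3 or 6 days. The groups came from the sample labels, which describe the wild type control as without drug and do not say whether controls received a vehicle. The labels do not say whether an array held RNA of 1 animal or of a pool, so p-values measure the spread between these arrays, which may in part be technical.

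The deposited values were intensities on a linear scale, in whole numbers, with 11.9% of them below 0. The authors had already brought the arrays to a common scale, as the deposited values show: the 2% trimmed means of the 8 arrays lay within 0.214% of their average. The method of that normalization, the background correction and the way probes were summarised into probe sets are not given in the sources used here. Intensities were therefore kept as deposited, under a rule that would have rescaled arrays more than 10% apart.

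Every intensity under 171, the 40th percentile of all values pooled, was set to 171, and log2 was taken. A value at this floor is only an upper limit, so a difference with 1 side at the floor is a lower bound on its size and is given as "at least". The table held 12488 probe sets, of which 66 were array controls and were kept for quality ratios. In the platform annotation 10855 probe sets had 1 gene symbol and 396 had several, and 1237 were not listed. Symbols of 10839 probe sets were updated through their gene numbers in the RefSeq gene table of the GRCm38.p6 assembly, which was used for names and for which genes neighbour each other. A probe set with 1 symbol was tested if at least 2 of 8 arrays exceeded the floor, which left 7346. The brightest probe set stood for each of the 6128 genes. Among the 1042 genes with several tested probe sets, 0 had probe sets that moved 2-fold in opposite directions at a treatment time. No column of values was left unused (0 columns).

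Changes at 8 hours, 3 days and 6 days were tested with limma 3.58.1 in R 4.3.3, in a fit of genotype plus time over all 8 arrays. This fit has 3 residual degrees of freedom and 2 arrays per time, 1 per genotype, so the residual spread holds noise and any difference between the genotypes in response. A log2 change is the mean over both genotypes from this fit, with its standard error, unless it is called the change in 1 genotype. The same fit gave the difference between genotypes, with 4 arrays each and time as a block. A further fit, with 2 residual degrees of freedom, tested whether the response to drug differed by genotype. P-values were adjusted by the Benjamini-Hochberg method over the 6128 genes with a threshold of 0.05. For a treated array set against the control array of its own genotype there is no replicate and no p-value, and 2-fold differences were counted. Wild type and knockout responses use separate control arrays.

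Before the data were examined, 27 gene lists were fixed, on lipid and energy metabolism, inflammation, cell division, stress, and markers of cell types and tissues that fat samples can hold. For each list the members passing over all genes and those passing when "adjusted over the list alone" were counted. The latter adjustment is made within 1 list and 1 comparison and does not correct for the number of lists or comparisons. The median change of a list in a single array was ranked among 10000 random lists of the same size matched on mean expression. Members at the floor entered a median at their bound. These percentiles, rounded to 2 decimals, describe these arrays and are not p-values. Genes named in the text also followed a fixed rule: Ppara; the 5 largest rises and 5 largest falls at each time among genes past the threshold that moved the same way in both genotypes; up to 6 genes each way that passed between genotypes with 1 direction at all 4 times; 6 genes each way for the interaction, filled by size where fewer passed; up to 4 members of each list with the largest change; and a fixed set of metabolic and inflammatory genes. Of that set, Ppargc1a and Ppard lay under the filter, and genes including Cpt1b, Gk, Adrb3, Gpnmb and Hbb-b1 had no single-gene probe set here. Where 6 or fewer members of a list passed, those outside the rule were named after their values were seen, as were the genes apart between genotypes at all 4 times and the pancreas genes outside the interaction test.

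The fits were tested on simulated data for 6128 genes, of which 200 were changed by known folds. Noise was normal, with spreads drawn as estimated by the limma fit to these data and limited from above. A change at a time was made at that time only and alike in both genotypes. Recovery depends on how many genes change, and 905 were called at 8 hours in the real data. The shares recovered therefore hold for these settings. Of genes changed 4-fold, 68% were recovered at 8 hours, 63% at 3 days, 70% at 6 days and 79% between genotypes. Of genes changed 2-fold, 12%, 5%, 7% and 44% were recovered in that order. The interaction fit recovered 0% of either size. Alternatives covered the scaling of the arrays, the floor, the filter, the choice of probe set, the limma prior, the block, and leaving out each array in turn. When 1 array is left out, its partner of the same time is fitted exactly, and residual degrees of freedom are lost. For comparisons that do not involve that time, and for the genotypes, leaving out either partner is therefore the same fit and not a separate check. Fits without both 6 day arrays, without both control arrays, or with only the controls and 1 time were chosen after seeing the data, as were the list counts without each array and their comparison at 1.5 times. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9.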

Results

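The series follows epididymal white fat through treatment with CL 316243, a selective agonist of the β3-adrenergic receptor, which in fat cells raises cyclic AMP and stimulates lipolysis. Tissue came from wild type mice and from mice lacking Ppara, the gene of PPARα, a nuclear receptor that is activated by fatty acids and drives genes of their oxidation. By its title the series sets the genotypes side by side along the time course. There were 8 arrays in 8 groups: a control, 8 hours after 30 nmol, and 3 days and 6 days at 3 nmol per hour, in each genotype. Array medians lay between 320 and 322 intensity units, and at least 39.9% of probe sets fell under the floor of 171 on each array. After filtering, 6128 genes were compared. With 1 array per group, the treatment effect was tested across genotypes and the genotype effect across times.

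Ppara, the targeted gene, was brighter on each wild type array than on any knockout array. Its intensities were 395 in the wild type control, 795 at 8 hours, 604 at 3 days and 1843 at 6 days. The knockout values were 214, 254, 292 and 336 in the same order. Knockout minus wild type was -1.51 ± 0.28 on the log2 scale over 4 arrays each, lower at all 4 times, with a limma adjusted p of 0.285, which does not pass. Where the probes of Ppara lie relative to the part removed in the knockout is not known here, so the residual signal in knockout arrays does not test the labels by itself.

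**Figure D1:**
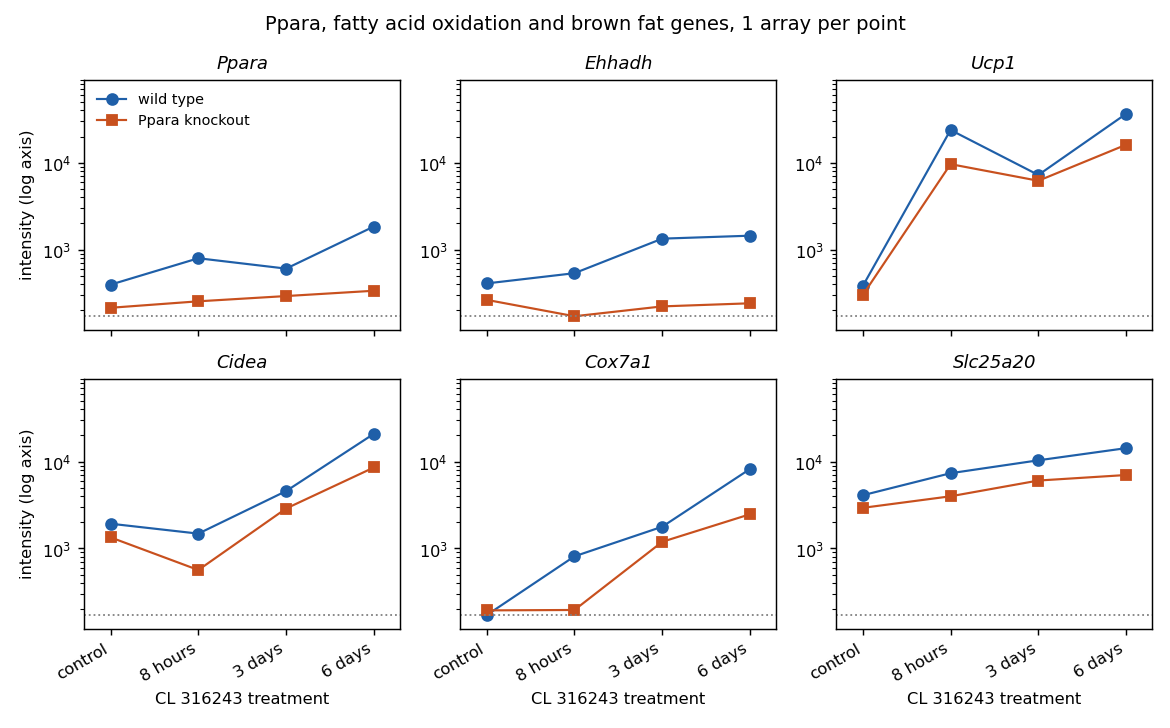
Intensity on a log axis of Ppara, Ehhadh, Ucp1, Cidea, Cox7a1 and Slc25a20 at each treatment, with circles for wild type, squares for Ppara knockout, 1 array per point and a dotted line at the floor of 171. Ehhadh reached 1445 in wild type and 241 in knockout at 6 days, and Ucp1 reached 36495 and 16088.

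Both control arrays were bright for genes typical of other organs. The knockout control was bright for epididymal genes, with Lcn5 at 52634, Clu at 35566, Gpx5 at 18291 and Adam7 at 12412, against 171, 2021, 303 and 171 in the wild type control. All 7 measured members of the epididymis and testis list were higher in the knockout control, with a median log2 difference of at least 5.17. The wild type control was bright for digestive enzymes of the pancreas, with Ctrb1 (chymotrypsinogen) at 24101 and Prss2 (trypsinogen) at 13345, against 363 and 171 in the knockout control. Knockout tissue at 8 hours also had Ctrb1 at 8261 and Gpx5 at 9017, and wild type tissue at 6 days had Gpx5 at 4949. The 5'/3' signal ratio of the Gapdh control probes was 0.793 in the knockout control and between 1.04 and 1.18 on the other 7 arrays. These differences enter every change measured against a control.

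**Figure D2:**
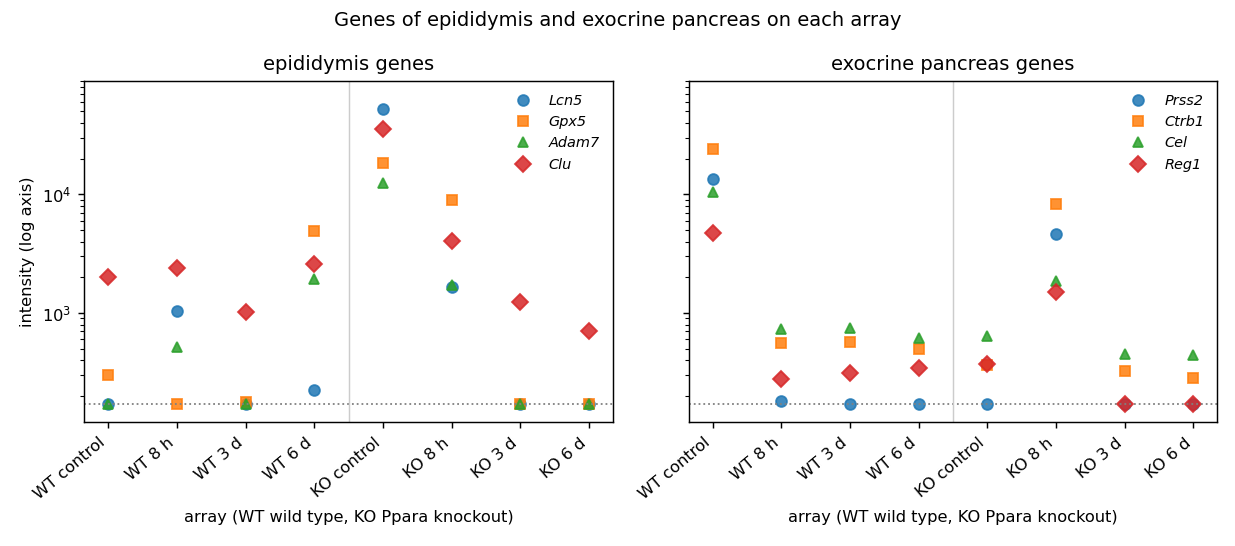
Intensity on a log axis of epididymal genes (left) and exocrine pancreas genes (right) on each of the 8 arrays, with the floor of 171 dotted. Lcn5 reads 52634 in the knockout control and 171 in the wild type control, and Prss2 reads 13345 in the wild type control and 4597 in knockout at 8 hours.

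At 8 hours the fat of both genotypes showed an inflammatory rise and a fall of adipocyte genes. The largest rises were in S100a9 (at least 5.85 ± 0.32) and S100a8 (5.69 ± 0.38), which encode the neutrophil protein calprotectin, the acute phase gene Saa3 (5.85 ± 0.85), Arg1 (at least 5.68 ± 1.15), which encodes arginase, and Ucp1 (5.48 ± 0.32), the uncoupling protein of brown fat. The largest falls were in Lep, the gene of leptin (-4.13 ± 0.28), the thyrotropin receptor gene Tshr (-4.09 ± 0.35, at least this far), Apcdd1 (-3.87 ± 0.27), Nnat (-3.87 ± 0.45) and Eepd1 (-3.82 ± 0.24). The limma adjusted p of these 10 genes ran from 0.00186 for S100a9 to 0.0298 for Arg1. In all, 397 genes rose and 508 fell, 905 together.

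Of the 39 measured acute inflammation genes, 28 rose, 1 fell and 10 did not pass, with 32 rises and 1 fall adjusted over the list alone. The list's median change was 2.37 in wild type and 2.06 in knockout, both at percentile 100 of random lists. Ccl2, a monocyte chemoattractant, rose by 4.83 ± 1.01, from 388 to 10021 in wild type and from 568 to 17763 in knockout. Il6 rose by at least 3.21 ± 0.23 and the interleukin 1 antagonist Il1rn by at least 3.80 ± 0.86, while the acute phase gene Orm1 fell (-1.64). Of 9 neutrophil genes, 5 rose (S100a8, S100a9, Il1r2, Mmp9 and Cxcr2), and over the list alone 5 rose and 1 fell. Of 37 macrophage genes, 5 rose: Arg1, Chil3 (at least 4.68 ± 0.66), Cd14, Mpeg1 and Fcgr2b. That count was 13 adjusted over the list alone. Of 28 immediate early and cyclic AMP response genes, 8 rose (9 over the list alone), led by Fosl1 (at least 3.73 ± 0.29), Ier3 (3.42 ± 0.32) and Junb (3.34 ± 0.50), and Fos stood at 2.42 ± 0.86 with an adjusted p of 0.114. Of 23 stress genes, 10 rose and 1 fell (16 and 2 over the list alone). Of 47 cell cycle genes, Cks2 and Tubb5 rose, and 2 rose over the list alone. Among the stress genes the heat shock gene Hsph1 rose by 2.62 ± 0.34 and the small heat shock gene Cryab fell (-1.84 ± 0.23).

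**Figure D3:**
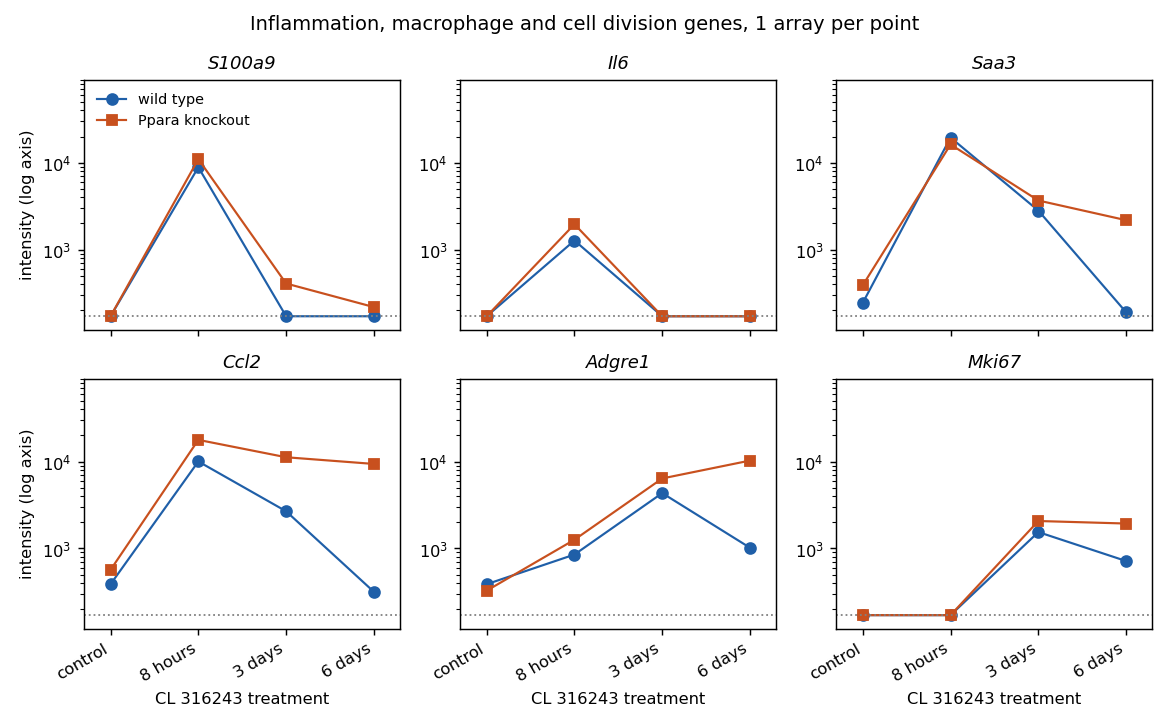
Intensity on a log axis of S100a9, Il6, Saa3, Ccl2, Adgre1 and Mki67 at each treatment, circles for wild type and squares for Ppara knockout, 1 array per point, floor of 171 dotted. Il6 lies at the floor on every array except those of 8 hours, at 1272 and 1958, and Ccl2 at 6 days reads 317 in wild type and 9387 in knockout.

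Genes that define the fat cell fell at 8 hours. Of 16 adipocyte identity genes, 12 fell and 0 rose, and 14 fell adjusted over the list alone. They included Lep, the insulin-responsive glucose transporter Slc2a4 (-3.15 ± 0.29), the hormone-sensitive lipase gene Lipe (-2.22 ± 0.35), Pparg (-1.28 ± 0.19) and Adipoq, the gene of adiponectin (-1.26 ± 0.23). Of 18 lipogenesis genes, 6 fell and 1 rose (7 and 1 over the list alone). Thrsp fell by 3.52 ± 0.30 and fatty acid synthase, Fasn, by 2.18 ± 0.27, while Dgat1, which makes triglyceride, rose (1.34). Of 17 genes of lipolysis and lipid handling, 6 fell and 2 rose (10 and 3 over the list alone). The falls included Lipe and G0s2 (-2.03 ± 0.34), an inhibitor of triglyceride lipase, and the rises were the lipid droplet gene Plin2 (1.51 ± 0.35) and the fatty acid binding protein Fabp5 (0.93 ± 0.19).

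Cholesterol synthesis genes moved the other way. Of 15 measured, 8 rose, and 10 rose and 1 fell over the list alone. They included Cyp51 (2.47 ± 0.27), Lss (2.28 ± 0.21), Idi1 (2.15 ± 0.27) and Msmo1 (1.94 ± 0.29). Their median change was 1.06 in wild type and 1.15 in knockout, both at percentile 100. Of 11 brown fat and thermogenic genes, 3 rose (Ucp1, the deiodinase Dio2 by at least 2.10 ± 0.36 and Elovl3 by at least 1.83 ± 0.36), and 3 rose and 1 fell over the list alone. Of 22 PPARα target genes, 3 rose (Pdk4 at 2.78 ± 0.40, Acaa1b at 2.11 ± 0.26 and Plin2) and 1 fell (Acadm at -0.99). Adjusted over the list alone, 3 rose and 2 fell. Pdk4, a kinase that restrains glucose oxidation, went from 2316 to 16701 in wild type and from 815 to 5340 in knockout.

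Oxidation genes went both ways at 8 hours. Among 16 peroxisomal oxidation genes, Acaa1b and Pex5 rose and Abcd2 (-3.30 ± 0.26), Cat and Hsd17b4 fell, which became 2 rises and 7 falls over the list alone. Among 15 mitochondrial fatty acid oxidation genes, 4 fell (Echs1 by 1.82 ± 0.23, Hadh, Acads and Acadm) and 0 rose, with 5 falls and 1 rise over the list alone. Of 22 TCA cycle genes, Pdk4 rose and Idh2, Sdha and Pcx fell, and over the list alone 1 rose and 3 fell. Of 59 oxidative phosphorylation genes, Cycs rose and Ndufv3 and Sdha fell, and 0 passed over the list alone. In glycolysis, with 16 genes, Slc16a1 (2.37 ± 0.23), Pgk1 (1.53 ± 0.17) and Pgam1 rose, and Slc2a4, Pfkm and Pfkfb3 (-1.68 ± 0.36) fell. Adjusted over the list alone, 5 rose and 3 fell.

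The 8 hour count moved with the arrays left out, where the fit also loses residual degrees of freedom. Leaving out the knockout 8 hour array left 0 genes, the knockout control 20, the wild type 8 hour array 27, either 3 day array 285 and the wild type control 457, while leaving out either 6 day array gave 1097. Without the filter on dim probe sets the count was 229. With any 1 array left out, adipocyte identity had 12 to 14 falls and cholesterol synthesis 7 to 10 rises over the list alone, and acute inflammation had 21 rises without the wild type 8 hour array and 27 to 33 otherwise. Over all genes these counts were less steady. Adipocyte identity falls numbered 0 without the knockout control or the knockout 8 hour array, 1 without the wild type 8 hour array, 5 without the wild type control or either 3 day array and 12 without either 6 day array. In the same order cholesterol synthesis rises numbered 0, 1, 6 and 4 (wild type control and 3 day arrays), and 8. Acute inflammation rises numbered 0 without the knockout 8 hour array, 6 without the knockout control or the wild type 8 hour array, 17 without either 3 day array, 19 without the wild type control and 31 without either 6 day array. Macrophage rises over the list alone numbered 1 without either control or either 3 day array, 0 without either 8 hour array and 25 without either 6 day array. Cell cycle rises numbered 0 without either control or either 8 hour array and 13 without either 6 day array. Over all genes these 2 lists had 22 and 9 rises without either 6 day array. Without the knockout control, falls over the list alone numbered 0 in lipid handling, 1 in mitochondrial fatty acid oxidation, 2 in lipogenesis and 3 in peroxisomal oxidation, and stress genes had 10 rises. Without the knockout 8 hour array these falls numbered 2 in each of the 4 lists. Without the wild type 8 hour array they numbered 3 in mitochondrial fatty acid oxidation, 4 in lipogenesis and 2 in peroxisomal oxidation. Without either 3 day array peroxisomal oxidation had 3, and without the wild type control lipid handling had 6. Of 37 counts of rises or falls over the list alone that were above 0 at 8 hours, 7 stayed within 1.5 times with any 1 array left out, and 19 reached 0 without at least 1 array.

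At 3 days Ucp1 and genes of cell division were among those that rose. The largest rises were in Ucp1 (4.31 ± 0.32), the proliferation marker Mki67 (at least 3.39 ± 0.38), the chemokine Ccl8 (3.39 ± 0.43), the acute phase gene Orm2 (at least 3.24 ± 0.42) and Birc5, the gene of survivin (at least 3.17 ± 0.43). The largest falls were in Nnat (-3.79 ± 0.45), the methyltransferase Inmt (-3.27 ± 0.24), Gm8096 (-2.75 ± 0.19), the matrix proteoglycan Fmod (-2.65 ± 0.23) and Folh1 (-2.57 ± 0.29). Inmt, Gm8096 and Fmod reached the floor, so they fell at least this far. The limma adjusted p of these 10 genes ran from 0.0178 to 0.0370. In all, 27 genes rose and 43 fell, and 1323 had an unadjusted p under 0.05. With the floor at the 25th percentile 14 rose and 17 fell, and with an intensity trend and robust prior 61 rose and 92 fell.

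Of 47 cell cycle genes, 6 rose at 3 days (Mki67, Birc5, Ccna2, Cks2, Kif22 and Hmgb2), and 41 rose adjusted over the list alone. All 47 had a positive change on each 3 day array, with medians of 1.52 in wild type and 1.76 in knockout. Of 37 macrophage genes, 0 passed over all genes and 31 rose adjusted over the list alone. Their median change was 1.85 in wild type and 2.27 in knockout, both at percentile 100. Adgre1, the F4/80 marker of macrophages, went from 388 to 4336 in wild type and from 327 to 6392 in knockout (3.89 ± 0.80, adjusted p 0.0830). Cd68, a lysosomal marker of macrophages, stood at 3.10 ± 0.67 (adjusted p 0.0851). Of 39 acute inflammation genes, 2 rose (Ccl8 and Orm2), and 4 over the list alone, with medians of 0 in wild type and 0.57 in knockout, the latter at percentile 100.

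Metabolic lists had few calls at 3 days. In the lists of peroxisomal oxidation and PPARα targets, Acaa1b rose (2.13 ± 0.26) and was the 1 call in each. Over the list alone 1 of 16 and 7 of 22 rose. Ucp1 was the 1 call among brown fat genes, with 6 of 11 over the list alone. Among mitochondrial fatty acid oxidation genes 0 of 15 passed, and 5 rose over the list alone. In lipid handling Fabp5 rose (1.51 ± 0.19) and Plin4 fell (-1.50), with 4 rises and 3 falls over the list alone. Lep fell (-2.52 ± 0.28), the 1 call of the adipocyte identity list, with 4 falls over the list alone. Pgk1 rose (1.19 ± 0.17) in glycolysis, with 3 rises and 1 fall over the list alone. Cryab fell (at least -2.09 ± 0.23) in the stress list, with 1 rise and 1 fall over the list alone. Oxidative phosphorylation, TCA cycle, lipogenesis and immediate early genes had 0 calls either way, cholesterol synthesis 1 rise and 1 fall and neutrophil genes 1 rise over the list alone.

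Without either 6 day array, or without both, the 3 day count was 441, with 34 cell cycle and 26 macrophage genes rising over all genes and 43 and 35 over the list alone. Leaving out either control, either 8 hour array or either 3 day array left 0 genes, as did dropping the filter on dim probe sets. Macrophage rises over the list alone then numbered 1 without the wild type control and 0 without the knockout control, either 8 hour array or either 3 day array. Cell cycle rises over the list alone numbered 15 without the knockout control, 20 without the wild type 3 day array, 26 without the knockout 3 day array, 30 without the wild type control and 40 without either 8 hour array. Mitochondrial fatty acid oxidation had 0 rises over the list alone without the wild type control or either 3 day array, 2 without either 8 hour array and 3 without the knockout control. PPARα targets had 3 without the wild type control, 2 without the knockout control or the wild type 3 day array and 0 without the knockout 3 day array. Brown fat genes had 1 without the wild type control, 2 without the wild type 3 day array and 3 without either 8 hour array. Acute inflammation had 10 without either 6 day array (8 over all genes), 2 without the knockout control or either 8 hour array and 0 without either 3 day array. Immediate early genes had 4 rises without either 6 day array, over the list alone and over all genes. Of 23 counts over the list alone that were above 0 at 3 days, 0 stayed within 1.5 times with any 1 array left out, and 19 reached 0 without at least 1.

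At 6 days 4 of the 5 largest rises were in genes of the brown fat list. The 5 were Ucp1 (6.16 ± 0.32), the cytochrome oxidase subunit genes Cox7a1 (at least 4.63 ± 0.54) and Cox8b (2.64 ± 0.36), Cidea, a lipid droplet gene of brown fat (3.05 ± 0.27), and Mki67 (at least 2.78 ± 0.38). Ucp1 went from 381 to 36495 in wild type and from 300 to 16088 in knockout. The largest falls were in Nnat (-3.38 ± 0.45), Folh1 (-3.24 ± 0.29), Gm8096 (-2.75 ± 0.19), Fmod (-2.61 ± 0.23) and the desmosome gene Pkp2 (-2.51 ± 0.19), with Gm8096 and Fmod again at the floor and their falls lower bounds. The limma adjusted p of these 10 genes ran from 0.00855 to 0.0457. In all, 14 genes rose and 37 fell, and 1116 had an unadjusted p under 0.05. With the floor at the 25th percentile 1 rose and 4 fell, and with an intensity trend and robust prior 52 rose and 76 fell.

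Of 11 brown fat and thermogenic genes, 4 rose (Ucp1, Cidea, Cox7a1 and Cox8b) and 6 rose adjusted over the list alone. Of 59 oxidative phosphorylation genes, 2 rose (Cox7a1 and Cox8b), and 8 over the list alone. Of 15 mitochondrial fatty acid oxidation genes, 1 rose, the carnitine carrier Slc25a20 (1.53 ± 0.20), and 11 rose over the list alone. Acadl, a long-chain acyl-CoA dehydrogenase, stood at 1.52 ± 0.23 (adjusted p 0.0561) and Etfdh at 1.64 ± 0.29 (adjusted p 0.0771). Slc25a20 was also the 1 call among 22 PPARα targets, with 9 rises over the list alone. For the TCA cycle 0 of 22 passed and 6 rose over the list alone. Among 47 cell cycle genes Mki67, Kif22 and Cks2 rose, and 29 over the list alone. For macrophage genes 0 of 37 passed either way, with medians of 0.39 in wild type and 2.69 in knockout. Plin4 (-1.46), Lep (-2.36 ± 0.28) and Cryab (at least -1.80 ± 0.23) fell in their lists of lipid handling, adipocyte identity and stress.

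Other lists at 6 days had few calls over the list alone. Lipid handling had 2 rises and 1 fall, adipocyte identity 2 falls, stress 2 rises and 3 falls, and glycolysis 3 rises. Immediate early genes had 1 rise and 1 fall, and lipogenesis 1 fall. Peroxisomal oxidation and acute inflammation had 1 rise each, and cholesterol synthesis and neutrophil genes 0.

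Without the wild type 6 day array the 6 day count was 285, and without either 3 day array it was 1. Leaving out either control, either 8 hour array or the knockout 6 day array left 0 genes, as did dropping the filter on dim probe sets. Without the wild type 6 day array macrophage genes had 24 rises over all genes and 35 over the list alone, acute inflammation 7 and 9, and immediate early genes 4 and 5. With any other array left out, macrophage rises over the list alone numbered 0 or 1, acute inflammation rises 0 or 1 and immediate early rises 0. Cell cycle rises over the list alone numbered 0 without either control and 8 without the knockout 6 day array, and over all genes 22 without the wild type 6 day array. Mitochondrial fatty acid oxidation and PPARα targets had 5 and 2 rises over the list alone without the wild type control, and 10 to 12 and 7 to 10 without any other array. Brown fat genes had 5 to 8 with any 1 array left out. Oxidative phosphorylation had 0 without the wild type control or the wild type 6 day array, 2 without either 3 day array, 3 without either 8 hour array or the knockout 6 day array and 13 without the knockout control. The TCA cycle had 0 without the wild type control, either 8 hour array or the wild type 6 day array, 1 without either 3 day array, 4 without the knockout control and 10 without the knockout 6 day array. Of 21 counts over the list alone that were above 0 at 6 days, 2 stayed within 1.5 times with any 1 array left out, and 14 reached 0 without at least 1.

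**Figure D4:**
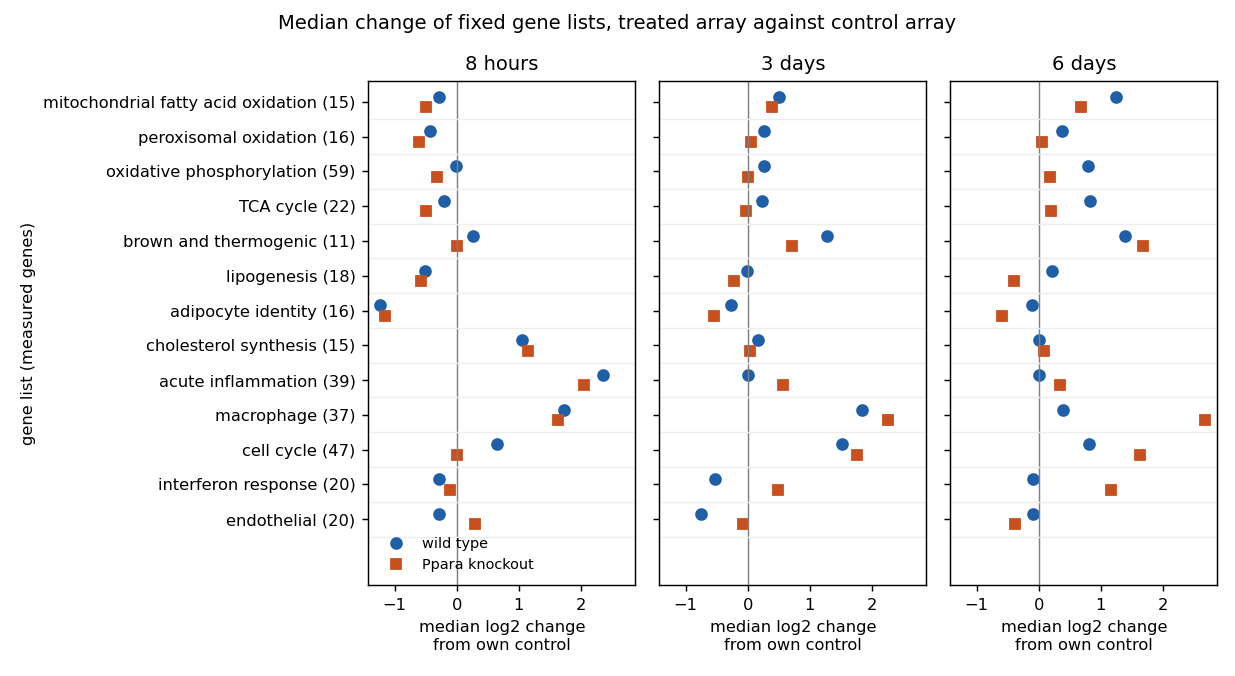
Median log2 change of 13 gene lists from the control array of the same genotype at 8 hours, 3 days and 6 days, circles for wild type and squares for Ppara knockout, with the number of measured genes in brackets. The macrophage list lies at 1.73 and 1.63 at 8 hours, and at 0.39 in wild type and 2.69 in knockout at 6 days.

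Each treated array was set against its own genotype's control, without a test since each comparison is 1 array against 1. The 2-fold counts have no replicate to be judged by, and the wild type and knockout controls were themselves 2-fold apart at 296 genes. In the knockout control 61 genes were at least 4-fold above the wild type control. Of these, 58 were brightest in the knockout control, which feeds the knockout counts of lower genes. In wild type 495 genes were at least 2-fold higher and 485 lower at 8 hours, 342 and 350 at 3 days, and 218 and 249 at 6 days. In knockout the counts were 687 and 673, 529 and 427, and 580 and 499. With the floor at the 25th percentile wild type had 493 and 574 at 3 days and 371 and 430 at 6 days. Knockout then had 750 and 675 at 3 days and 795 and 775 at 6 days. Across genes, which are not independent replicates, the wild type and knockout changes correlated with Pearson's r of 0.66 at 8 hours, 0.60 at 3 days and 0.30 at 6 days. At 8 hours 341 genes were at least 2-fold higher in both genotypes, where independent lists would share 55.5. At 6 days 80 were, against 20.6. Between 3 and 6 days, 124 genes were at least 2-fold higher and 230 lower in wild type, and 27 and 26 in knockout. The knockout 3 and 6 day arrays were the closest pair of all, with r of 0.987 across genes.

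The genotypes stood furthest apart at 6 days. Knockout tissue was at least 2-fold higher for 571 genes and lower for 353, compared with 200 and 96 in the controls, 108 and 89 at 8 hours and 155 and 87 at 3 days. Of 37 macrophage genes, 36 were at least 2-fold higher in knockout at 6 days, with a median log2 difference of 2.29 at percentile 100, against 0.52 at 3 days. From 3 to 6 days the median of this list moved by -1.47 in wild type and 0.25 in knockout. Adgre1 at 6 days was 1019 in wild type and 10264 in knockout, Cd68 was 2515 and 18755, and Ctss, a lysosomal protease, was 6819 and 25851. Ccl2 was 317 and 9387, and Arg1 lay at the floor in wild type and at 4818 in knockout. Cell cycle genes had a median difference of 1.22, with 27 of 47 at least 2-fold higher in knockout. Interferon response genes had 0.86 at 3 days and 0.99 at 6 days. On the lower side in knockout at 6 days were TCA cycle genes (median -0.88, all 22 lower), mitochondrial fatty acid oxidation (-0.93, 14 of 15), oxidative phosphorylation (-0.66, 56 of 59) and lipogenesis (-0.86, 17 of 18). Adipocyte identity genes had a median of -0.52 (all 16 lower) and endothelial genes -0.82, while fibroblast and matrix genes had 0.34, with 25 of 37 higher. Elovl6, a fatty acid elongase, was 3815 in wild type and 697 in knockout.

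Tested over all 4 times, 0 genes passed between the genotypes, and several lists of oxidation genes had members lower in knockout when adjusted over the list alone. The limma fit had 940 genes with an unadjusted p under 0.05, 323 higher and 617 lower in knockout, where chance gives 306, and the smallest adjusted p was 0.285. Of 15 mitochondrial fatty acid oxidation genes, 11 were lower in knockout adjusted over the list alone, with list medians of -0.28 in the controls, -0.68 at 8 hours, -0.51 at 3 days and -0.93 at 6 days. Examples are Etfdh (-0.86 ± 0.20), Acadl (-0.84 ± 0.16) and Slc25a20 (-0.79 ± 0.14). Over their lists alone, 12 of 16 peroxisomal oxidation genes, 11 of 22 PPARα targets, 11 of 22 TCA cycle genes, 11 of 18 lipogenesis genes, 10 of 17 lipid handling genes, 8 of 11 brown fat genes and 3 of 16 adipocyte identity genes were lower in knockout. Glycolysis had 1 of 16 lower. For oxidative phosphorylation 0 of 59 passed over the list alone, with a median of -0.36. Markers of cell types differed along with these lists, although few or none passed: adipocyte identity genes had a median of -0.37, all 16 lower, and macrophage genes 0.70, all 37 higher (0.20 without either 6 day array). The lower oxidation genes are therefore not separated here from a difference in the cell make-up of the samples. These counts over the list alone moved when arrays were left out. With time as a block, an array whose partner of the same time is left out no longer bears on the genotype difference. Leaving out either array of a time, or both, is therefore the same fit, with fewer residual degrees of freedom. Without either 8 hour array, lipogenesis had 2 and the other lists named here 0. Without either 3 day array, mitochondrial fatty acid oxidation had 6, PPARα targets 9, the TCA cycle 1 and the others 0. Without either 6 day array, or both, mitochondrial fatty acid oxidation had 9, PPARα targets 6, lipogenesis 5 and the others 0. Without either control, or both, mitochondrial fatty acid oxidation had 13, peroxisomal oxidation 12, the TCA cycle 16, lipogenesis 12, PPARα targets 8, brown fat genes 7, adipocyte identity 1 and lipid handling 0, and 4 interferon response genes were higher in knockout. All 9 of the counts over the list alone reached 0 without at least 1 array.

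The 5'/3' signal ratios of control probes, a sign of RNA quality, differed between the genotypes in directions that depended on the probe. The 5'/3' signal ratio of the pyruvate carboxylase control probes was 0.0388 in knockout and 0.292 in wild type in the controls, 0.115 and 0.270 at 8 hours, 0.284 and 0.406 at 3 days, and 0.211 and 0.413 at 6 days. Actin went the other way, with 0.645 in knockout and 0.635 in wild type in the controls, 0.784 and 0.755 at 8 hours, 0.869 and 0.782 at 3 days, and 0.827 and 0.700 at 6 days. Gapdh was lower in knockout in the controls (0.793 and 1.04) and at 8 hours (1.05 and 1.16), higher at 3 days (1.18 and 1.14) and level at 6 days (1.15 and 1.15).

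Ehhadh, the bifunctional enzyme of peroxisomal β-oxidation, was lower in knockout at each time (at least -1.86 ± 0.35, adjusted p 0.285), with 408, 535, 1336 and 1445 in wild type and 264, 171, 222 and 241 in knockout. Pdk4 (-1.13 ± 0.28), Slc2a4 (-1.16 ± 0.21) and Fasn (-0.79 ± 0.19) had negative differences too, and Fos was higher on average (2.02 ± 0.61, adjusted p 0.291). A fixed size of 1.5-fold at all 4 times in 1 direction was met by 20 genes, 8 higher and 12 lower in knockout. Among the lower ones were Ehhadh, Ppara, the malic enzyme Me1 (-1.05 ± 0.14), Dhrs7 (-0.98 ± 0.17) and Pcx. Among the higher ones were Clta (1.61 ± 0.17), Tes (at least 1.38 ± 0.22) and Fkbp11 (1.19 ± 0.14). Pcx is the gene of pyruvate carboxylase, whose control probes are described above. In the wild type and knockout controls its 3' control set read 18042 and 11869, and its 5' set 5268 and 460. The size of its difference thus depends on the end of the transcript that is read.

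Whether the response to drug differed by genotype was tested with the controls set against all 3 treated times. With limma 0 genes passed, 625 had an unadjusted p under 0.05, and the smallest adjusted p was 0.231. That count depends on the filter, since 176 of 8251 genes passed when dim probe sets were kept. This fit takes up the control pair exactly, so a gene above the floor on 1 control array alone has no residual spread. How many of the 176 are such genes was not counted, so they are not read as differences in response. The largest differences, none of which passed, belonged to genes far apart between the control arrays, several of them genes of the other organs named above. The difference is measured from 1 control pair, so such genes head the ranking by its form. Their rank is therefore no separate sign of other tissue in the controls. Wild type response minus knockout response was most positive for Lcn5, Adam7, Prm1, Gpx5, C4bp and Cyb561, each brightest in the knockout control. It was most negative for the pancreas genes Prss2, Ctrb1, Cela2a, Clps and 2210010C04Rik and for Zg16, each brightest in the wild type control. Adjusted over the list alone, 6 of 7 epididymis and testis genes and 3 of 11 mesothelium genes passed, as did 1 gene each of the acute inflammation, macrophage, neutrophil, lipogenesis and erythrocyte lists. The fit found 0% of 4-fold differences in simulated data, so a count of 0 does not show that responses were alike.

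Lists of other cell types had few calls. Of 20 endothelial genes, Mcam fell at 8 hours (-1.47 ± 0.27). Over the list alone 1 fell at 8 hours and 2 at 3 days and at 6 days. Of 37 fibroblast and matrix genes, Tnc (at least 1.87 ± 0.47), Mmp3 and Lamb1 rose and Dpt fell at 8 hours. Over the list alone 2 rose and 1 fell then, 1 rose and 3 fell at 3 days, and 4 fell at 6 days. Of 12 lymphocyte genes, Ighm (-2.30 ± 0.32) and Zap70 (at least -0.86 ± 0.20) fell at 8 hours, and 2 fell over the list alone. Of 7 mast cell genes, Hdc, the histamine-forming enzyme, rose at 8 hours (2.69 ± 0.30), 1 call over the list alone too. Of 11 mesothelium genes, Slpi rose at 8 hours (2.67 ± 0.52) and Upk3b fell at all 3 times. Over the list alone mesothelium had 1 rise and 1 fall at 8 hours, 1 rise and 4 falls at 3 days and 4 falls at 6 days. Krt18, of that list, was bright in the knockout control at 2716 against 245 in the wild type control. Of 14 skeletal muscle genes, Myl1 fell at 8 hours (-1.84 ± 0.35), and 1 fell over the list alone. Of 20 interferon response genes, Cxcl9 fell at 8 hours (at least -2.06 ± 0.38), and 1 fell over the list alone. None of the 7 epididymis and testis, 7 erythrocyte and 8 MHC class II genes passed over all genes at any time, and over the list alone 1 of the MHC class II genes rose at 3 days and at 6 days.

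These counts moved with single arrays too, the controls among them. Without the wild type control, 4 of the 7 epididymis and testis genes fell over all genes at 8 hours, and 5, 6 and 5 fell over the list alone at 8 hours, 3 days and 6 days. Mesothelium falls over the list alone then numbered 4, 7 and 6, and fibroblast and matrix genes had 5 rises and 0 falls at 8 hours, 9 rises and 1 fall at 3 days and 0 of either at 6 days. Without the knockout control, mesothelium falls numbered 1, 2 and 2, and fibroblast and matrix genes had 0 calls at each time. Fibroblast and matrix rises at 3 days numbered 3 without either 6 day array and 0 without either 8 hour or either 3 day array. Endothelial falls over the list alone numbered 0 at each time without either control, either 8 hour array or the wild type 3 day array, and 4 at 6 days without the wild type 6 day array.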

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

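The tests on epididymal genes, macrophage genes and genes apart at all 4 times, and the splits that keep 1 array of each time per group, were chosen after the results were seen, while the pancreas marker test and the splits of all 8 arrays were set beforehand.

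Outside the tested genes, the array's 3' control probe set for the transferrin receptor was at least 15.1-fold above control at 6 days as a mean of both genotypes, at least 22.9-fold in wild type and at least 9.96-fold in knockout on floored values. The tested gene Tfrc stood at 1.10 on the log2 scale at 6 days with a limma adjusted p of 0.108. Of 1589 probe sets with no single gene name, 11 were at least 4-fold above control at 8 hours in both genotypes. No group held 4 arrays, so no array was tested as an outlier of its group.

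Genes of other organs were bright on the control arrays. Epididymal tissue in the knockout control is a candidate source: the epididymis and testis list, fixed beforehand, was higher there by a median of at least 5.17, all 7 members, with Lcn5 at 52634 and Clu at 35566, although 2 of the 7 lay above the floor on all 8 arrays. Pancreatic tissue in the wild type control is a candidate source too: 8 markers, other than the pancreas genes in which the pattern was first seen, were all higher there, by a median of at least 3.24, with Cel at 10375 and Reg1 at 4749, and 2 of the 8 lay above the floor on all arrays. An effect of the knockout at every time is argued against, since the epididymal median of knockout minus wild type was 0 at 3 days and -0.85 at 6 days, after 0.67 at 8 hours. Some of these genes were bright on treated arrays too. Knockout tissue at 8 hours had Prss2 at 4597 and Gpx5 at 9017, and wild type tissue at 6 days had Gpx5 at 4949. Lcn5 read 1663 and 223 on those arrays. A genotype effect confined to the controls does not cover such arrays. For the controls it was not tested and stays open.

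Macrophage genes were high in the knockout 6 day array. A lower share of fat cells would raise other cell types alike, and is argued against as the only cause. Endothelial genes were lower in knockout at 6 days, with a median of -0.82 and an upper quartile of -0.32. The lower quartile of the macrophage genes was 1.92. Part of the endothelial gap was present in the controls, with a median of -0.55 and 18 of 20 lower, where the macrophage median was 0. From their own controls endothelial genes moved by -0.09 in wild type and -0.38 in knockout at 6 days, so they showed no rise there either. On the other side, adipocyte identity genes were lower (median -0.52, all 16) and fibroblast genes higher (median 0.34). A second measurement of the 3 day RNA is argued against as well, because brown fat genes were higher at 6 than at 3 days in knockout, by a median of 0.52 at percentile 100 of random lists, 8 of 11 genes. A sample of the 3 day state under the 6 day label cannot be told apart from a slower course in knockout. The changes from 3 to 6 days correlated at -0.03 across genes between genotypes, and both readings allow that. List medians went both ways. In wild type and knockout they moved by 0.46 and 0.20 for oxidative phosphorylation and by 0.61 and 0.18 for the TCA cycle. Endothelial genes moved by 0.65 and -0.17. Each value rests on single arrays and does not decide between the readings. An effect of the genotype stays open and was not tested, and the gap rests on 2 single arrays, since the macrophage median moved by -1.47 from 3 to 6 days in wild type and by 0.25 in knockout.

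The 20 genes at least 1.5-fold apart at all 4 times may follow the genotype, and a difference in strain was not tested. Carried-along neighbours of Ppara are argued against as the common cause, since 0 of the 19 other genes lay among the 50 tested genes nearest to Ppara and 1 lay on chromosome 15, where even spread gives 0.807. Of 8 splits with 1 array of each time per group, 1 (the real one) gave as many genes and the highest other gave 16. That split swaps only the controls, so it still sets wild type against knockout at the treated times, and the next gave 8. In any case 8 splits are too few for a share under 0.05.

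For the genotype test as a whole, 3 of 32 splits with time as a block, the real one included, gave as many genes at an unadjusted p under 0.05 as the real 940, and the highest other gave 1555. Both other splits put the controls on 1 side and the 8 hour arrays on the other, which leaves wild type against knockout at 3 and 6 days, so they are 1 fit and say nothing on chance. Of the 8 splits that keep 1 array of each time per group, 1 (the real one) gave as many, and the highest other gave 761. That split swaps only the controls, so it still sets wild type against knockout at the treated times, and the next gave 345. In any case 8 splits are too few for a share under 0.05. In 3 of the 35 possible splits the model could not be fitted.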

How the results depend on the processing

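Averaging probe sets kept each count of changed genes within 1.5 times of that reported. So did scaling to equal medians and quantile normalization, but the deposited arrays already had nearly the same distribution of values. Their medians lay between 320 and 322, and their shares of probe sets under the floor between 39.9% and 40.01%. Those rescalings could therefore change little, and do not test how the counts depend on normalization. Fits without both 6 day arrays, without both control arrays or with only the controls and 1 time were chosen after seeing the data. With the floor at the 25th percentile, 602 genes changed at 8 hours, 31 at 3 days and 5 at 6 days, and the 2-fold counts in wild type were 1067 at 3 days and 801 at 6 days. With a pseudocount in place of the floor, 46 changed at 3 days. With no filter on dim probe sets, 229, 0 and 0 changed at 8 hours, 3 days and 6 days, with 8251 genes tested. In the interaction 176 passed, where a gene above the floor on 1 control array alone has no residual spread. With an intensity trend and robust prior, 153 changed at 3 days and 128 at 6 days. Without the genotype block the counts were 542, 45 and 29. With only the arrays of the controls and that time, 0 changed at each time, with fewer arrays in the fit. Without both 6 day arrays 441 changed at 3 days. Leaving out each array in turn gave 0 to 1097 genes at 8 hours, 0 to 441 at 3 days and 0 to 285 at 6 days, with 0 between genotypes and 0 for the interaction in each case. The interaction could not be fitted without either control. For the other changes the cause was not tested. All 87 named changes past the threshold kept their direction in every alternative. Of these, 18 kept their side of the threshold under all preparations, under the other prior and without the genotype block. Every called gene had moved the same way in both genotypes, 905 at 8 hours, 70 at 3 days and 51 at 6 days. A kept direction is therefore likely from the selection alone when 1 array is left out. The mean of a list's wild type and knockout medians was compared with the reported one for each list, time and alternative preparation. In 458 of these comparisons it stayed within 1 SD of the wild type and knockout medians, and in 28 it moved. That SD is taken over just the wild type and the knockout median. It is widest where the genotypes differ most, so the 458 say little on how steady the medians are. Among called genes at 8 hours, 169 of 905 had an array at the floor, where fold sizes are bounds.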

Other observations

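All tests of this part were chosen after the results were seen, and none is a test between replicates. Among genes of the lipid droplet and fatty acid transport, Plin2 was 15158 in wild type and 36946 in knockout at 6 days, after 25671 and 35619 at 3 days. Hmox1, which degrades haem, was 2951 and 10914 at 6 days, and the matrix gene Postn was 5357 and 13485. The interferon response list had a median change from the own control of -0.52 at 3 days in wild type and 0.49 in knockout, with Iigp1 at 271 and 1046. Endothelial genes had a median of knockout minus wild type of -0.55 in the controls, 0.24 at 3 days and -0.82 at 6 days.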
